A study of Gallus gallus and Coturnix japonica with 6 samples.

How the data were processed

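Genomic DNA was extracted from the liver of 3 female chickens (WL-G) and 3 female Japanese quail and labelled with biotin from 0.3 µg of DNA by random-primed synthesis, per the labels. Each bird was hybridised to 1 Affymetrix chicken array. The authors obtained 1 signal per probe set with the Affymetrix software GCOS 1.4, and the deposited values are linear intensity. The algorithm, the scaling setting and detection calls are not stated in the labels. The deposited intensity values were checked and were not scaled to a common level between arrays, while added spike-in probe sets had nearly equal values on all 6 arrays. The table held 38535 probe sets, of which 96 were controls (27 spike-in, 59 null and 10 chicken gene controls) and 38439 were tested.

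Samples were grouped by species and treated as unpaired. Deviations of probe sets from the species mean did not correlate between a chicken and a quail of the same replicate number (r = -1e-04, -0.0048 and 0.0016). Centred values were used, so this check cannot see effects on whole arrays. Spike-in mean log2 signals were close by number. They were 11.87, 11.77 and 11.70 in chickens 1 to 3 and 11.90, 11.77 and 11.71 in quail 1 to 3. A pairing of arrays by number is therefore not excluded. Each array was divided by its median over the tested probe sets and multiplied by the geometric mean of the medians. Values below 1 were set to 1, log2 was taken, and each array was centred on its median. Quail minus chicken was tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), at a Benjamini-Hochberg adjusted p under 0.05. A probe set counted as retained when the lower end of the 95% confidence interval of its log2 ratio lay above -1. This scaling was chosen before the data were examined, when it was not known that the values were unscaled, so the counts are also given on the deposited scale, which keeps the difference in total signal between species.

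A gene symbol stood at 27168 probe sets, several symbols at 177 and none at 11094. Of these, 26853 matched the RefSeq annotation of the chicken assembly GRCg7b, which gave chromosomes and changed 0 symbols. For genes, the probe set with the highest mean over the 6 arrays was used, which gave 13009 genes. Gene lists were defined by patterns of symbols before the data were examined. Of 25 lists 20 were tested with camera (preset correlation 0.01), against all other genes, with adjustment over the lists. The beta-defensin, mitochondrial genome and W-linked lists had 1, 0 and 1 members, under the minimum of 5. A pair of lists defined by gene titles could not be run because titles were not available. The counts of members are given over all probe sets tested and adjusted over the list alone. Calls of camera were repeated with an estimated correlation and with fry, which tests whether the genes of a list move 1 way on balance and does not compare them with other genes.

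Named genes were chosen by a rule set before the data were examined. Among probe sets with 1 symbol not starting with LOC, an adjusted p under 0.05, at least a 2-fold difference, no overlap between species and a mean above the array median, the 10 lowest and 10 highest were taken. The 2 lowest and 2 highest members of each tested list and the members of the photoperiodic axis list were added. Values of single arrays or classes were compared by exact two-sided permutation tests of the 6 arrays, whose smallest p is 0.1. The level of background was set, after the data were seen, at the 95th percentile of the null controls of each array. Where all birds of a species lay at or below it, the fold is a lower bound on the deposited scale, and no fold is given where both species did.

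Alternatives were values as deposited, quantile normalization, centring on the 75th percentile or on the spike-ins, 16 or 64 units added before the logarithm, only probe sets with a mean above the 25th percentile or the median, eBayes without the trend or with a robust one, replicate number as a block, only names ending in _at, the mean of all probe sets of a gene, and each array left out in turn. Deposited values with 16 units added, only probe sets with chicken signal above the null controls, and lists without members outside their name were added after the data were seen. The analysis was tested on simulated data made from the chicken means and the noise between birds. With 200 changed probe sets, 0% of 1.5-fold, 0% of 2-fold and 9.68% of 4-fold changes were recovered. With 15376 changed, 15.3%, 43.4% and 77.7% were recovered, and 247 of 7242 calls (3.41%) were false. A list moved by 0.5 was called with a shift of 0.60, and 0 other lists were called. All other genes had no species difference in that simulation, unlike the real data. It therefore does not show how often camera would call or miss a list here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.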

Results

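Genomic DNA from the liver of 3 female chickens and 3 female Japanese quail was hybridised to Affymetrix arrays of chicken sequences, 1 array per bird. The birds were 8 weeks old and had been kept under 18 h of light and 6 h of dark per day, without treatment. The comparison asks which chicken probe sets also give signal with quail DNA. Each array gave 1 signal for each of 38439 probe sets, and a further 96 control probe sets were kept apart. A gene symbol was attached to 27168 of the probe sets, which represent 13009 genes. The number of birds, 3 per species, limits the precision of every value below.

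Quail DNA gave less signal than chicken DNA across most of the array. The median signal of the deposited values was 53.3 ± 3.12 (SD, n = 3) intensity units in chicken and 20.5 ± 2.84 (SD, n = 3) in quail, a 2.60-fold difference. The 25th percentile was 33.3 ± 2.11 in chicken and 7.78 ± 0.983 in quail, a 4.29-fold difference, and the 75th percentile was 76.4 ± 4.41 in chicken and 39.2 ± 5.45 in quail, a 1.95-fold difference (SD, n = 3 each). The bacterial and phage spike-in probe sets, whose targets are added at hybridisation, had geometric means of 3524 ± 214 and 3547 ± 243 units (SD, n = 3). An exact two-sided permutation test of the 6 arrays gave p = 0.1 for the median signal and p = 0.7 for the spike-ins. The smallest p that 3 birds against 3 can give is 0.1, so these single values cannot reach 0.05. In chicken 88.6% ± 1.44 of probe sets lay above the 95th percentile of the null control probe sets on the same array, against 56.3% ± 4.74 in quail (SD, n = 3, exact permutation p = 0.1, the smallest possible). Of 32027 probe sets above that level in all 3 chickens, 15773 (49.2%) were above it in all 3 quail and 7395 (23.1%) were within it in all 3 quail.

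**Figure D1:**
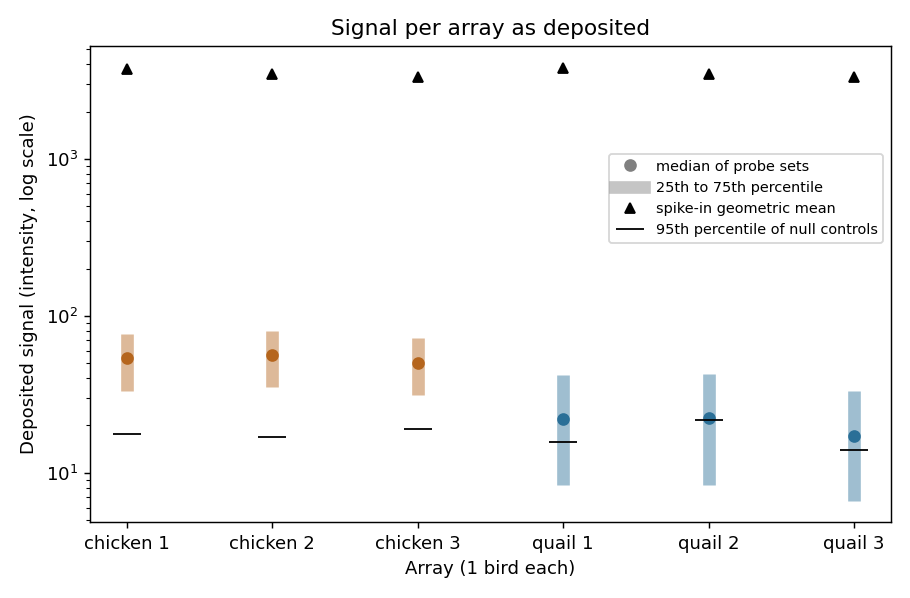
Deposited signal on a log axis for each of the 6 arrays, 1 bird each. Points are medians over 38439 probe sets, thick bars run from the 25th to the 75th percentile, triangles are spike-in geometric means and dashes the 95th percentile of the null controls. The quail medians lie between 17.3 and 22.4 and the chicken medians between 50.02 and 56.2, while the spike-ins lie between 3335 and 3815 on all 6 arrays.

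Birds of a species resembled each other far more than birds of different species did. Across probe sets, which are not independent replicates, Pearson's r of the median-centred log2 signal was 0.877 to 0.888 between chickens, 0.786 to 0.800 between quail and 0.490 to 0.501 between a chicken and a quail. The median SD over probe sets was 0.24 (log2, n = 3) within chicken and 0.46 within quail. Among the 19219 probe sets with the higher mean signals it was 0.20 and 0.32. The median absolute difference between species was 0.87, beyond the spread within either species. The values of the 3 chickens and the 3 quail did not overlap at 21195 probe sets (55.1%), where chance gives 10%.

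The first comparison asked which probe sets gave less or more signal with quail DNA than the rest of the array did. With each array centred on its own median, limma called 6012 probe sets lower and 9415 higher in quail (Benjamini-Hochberg adjusted p under 0.05). At least a 2-fold difference was seen at 5611 of the lower and 6306 of the higher ones. This split depends on the scale. On the deposited scale, where the median log2 ratio was -1.23 instead of 0.15, 22863 probe sets were lower and only 421 higher, so that 98.2% of the calls were lower against 38.97% after centring. All 6012 probe sets called lower after centring were also lower on the deposited scale, and 421 of those called higher were also higher there. A further 7828 of the latter were not called on the deposited scale and 1166 were called lower. For most probe sets, a call of higher after centring therefore means a higher ratio than that of the array medians, without a called difference on the deposited scale. The higher calls after centring also include probe sets near the null controls in both species. With only the 32027 probe sets above the null controls in all 3 chickens, a choice made after the data were seen, 6103 were lower and 8326 higher. The 2-fold counts on the deposited scale were 20035 lower and 320 higher. The middle of the deposited log2 ratios ran from -2.26 at the 25th percentile to -0.51 at the 75th, and the 5th and 95th percentiles were -4.06 and 0.35. The lower end of limma's 95% confidence interval of the log2 ratio lay above -1 at 21671 probe sets (56.4%) after centring and at 6424 (16.7%) on the deposited scale. After centring this limit is relative to the array medians, and on neither scale does it require signal in chicken. Of the 32027 probe sets above the null controls in all 3 chickens, 18143 met it after centring. Without chicken replicate 1, 2 or 3 the count of lower probe sets was 3247, 3150 and 3246, and that of at least 2-fold lower ones 3170, 3081 and 3168. With 16 units added before the logarithm, at least 2-fold differences after centring were called at 3233 lower and 3082 higher probe sets, and with 64 units added at 342 and 383. With the arrays centred on their 75th percentile instead, the balance turned, with 8980 probe sets lower and 4697 higher.

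The 10 lowest ratios among named probe sets with a mean above the array median came from probe sets within the null controls in all 3 quail and bright in chicken, as that limit on the mean requires. Some dimmer named probe sets with centred ratios as low were left out by it. ARL2BP, which encodes a binding partner of the small GTPase ARL2, had 768 ± 93.7 units in chicken and 4.27 ± 3.55 in quail (SD, n = 3), at least 45.5-fold lower when the quail value is set to the null control level (limma adjusted p = 0.000102). LIMS1, a focal adhesion adaptor also known as PINCH, was represented by 3 of these 10 probe sets, with chicken means of 472, 495 and 473 units and quail means of 2.78, 5.61 and 5.02. These probe sets were at least 28.0-fold, 29.4-fold and 28.1-fold lower in quail. C3H2ORF3 had 432 ± 40.8 and 4.31 ± 4.74 units (SD, n = 3), at least 25.6-fold lower in quail. A pair of probe sets of TARP, from the T-cell receptor gamma locus, had 365 and 400 units in chicken and were at least 21.7-fold and 23.7-fold lower. The remaining ones belong to chicken immunoglobulin-like receptors, a multigene family of leukocyte receptors. CHIR-IG1-5 had 585 ± 52.0 units in chicken and 5.27 ± 1.26 in quail (SD, n = 3), at least 34.7-fold lower. The CHIR-A2 probe sets had 566 and 433 units in chicken and were at least 33.6-fold and 25.4-fold lower. All 10 were called lower on both scales. Of 28 other probe sets of these 6 genes, 20 were lower and 0 higher after centring, and 25 were lower and 0 higher on the deposited scale. The 8 not called after centring were all of TARP, where 9 of 17 others were lower after centring and 14 on the deposited scale. HINTW, a gene of the female-specific W chromosome that was singled out after its values were seen, had 366 and 411 units at its 2 probe sets in chicken and 17.1 and 48.4 in quail (limma adjusted p = 0.00373 and 0.000363).

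At the other end, the 10 probe sets of 9 genes chosen by the same limits gave more signal with quail DNA on both scales. DMRT3, a DM-domain transcription factor gene on chromosome Z, had 8.72 ± 6.61 units in chicken, within the null controls, and 196 ± 55.3 in quail (SD, n = 3), at least 10.7-fold higher (limma adjusted p = 0.000530). ZNF236, a zinc finger gene, had 8.52 ± 2.51 and 144 ± 29.4 units (SD, n = 3), at least 8.005-fold higher. AGBL1, a cytosolic carboxypeptidase gene, had 44.6 ± 4.56 units in chicken and 718 ± 154 in quail (SD, n = 3), 15.9-fold higher on the deposited scale. MANBAL13 was 15.7-fold higher, with 28.6 ± 0.761 and 453 ± 64.2 units (SD, n = 3). AFF4, a scaffold of the super elongation complex, was 11.7-fold and 6.97-fold higher at 2 probe sets, with quail means of 842 and 577 units. ANKRD26 was 11.2-fold, C12orf10 8.15-fold and ITCH (a ubiquitin ligase) 6.69-fold higher on the deposited scale. NUP153, a nuclear pore protein, had 16.8 ± 8.68 units in chicken, where 2 of 3 birds lay above the null controls, and 106 ± 4.52 in quail (SD, n = 3). The adjusted p of these 10 lay below 0.05 on both scales. Except for AFF4, DMRT3 and NUP153, with 2 probe sets each higher on both scales, these values belong to single probe sets. Of 26 other probe sets of the 9 genes, 12 were lower and 2 higher on the deposited scale, and 0 were lower and 7 higher after centring. Those lower on the deposited scale were 5 of 8 for ZNF236, 4 of 5 for ANKRD26, 2 of 3 for ITCH and 1 of 2 for NUP153, whose other one was higher. A further probe set of MANBAL13 and of AGBL1 gave deposited log2 ratios of 0.31 and -0.10, both past the threshold only after centring. Another DMRT3 probe set was higher on both scales, with 41.8 units in chicken and 177 in quail, and the remaining one gave 13.4 and 12.8 units. Of 7334 genes with several probe sets, 929 had calls in both directions after centring.

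**Figure D2:**
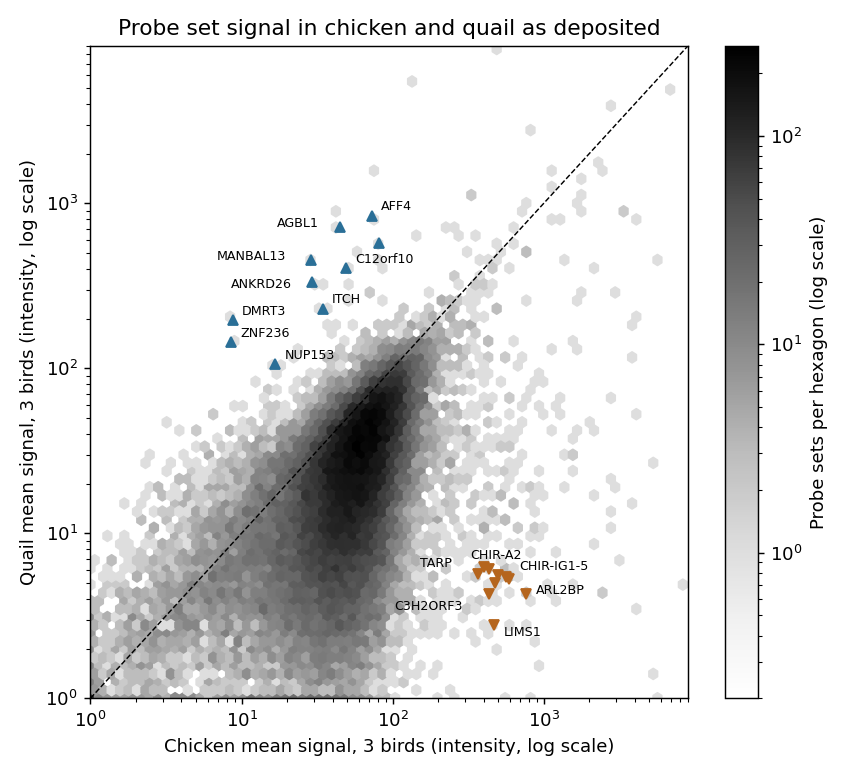
Mean deposited signal of each probe set in 3 chickens (x axis) and 3 quail (y axis), both log axes, with means below 1 drawn at 1 and the number of probe sets per hexagon in grey. The dashed line marks equal signal, down triangles the 10 lowest and up triangles the 10 highest centred ratios among named probe sets with a mean above the array median. Most probe sets lie below the line, and the triangles lie far from it, with ARL2BP at least 45.5-fold lower and AGBL1 15.9-fold higher in quail as deposited.

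Gene groups were compared next, with 1 probe set per gene. Over 13009 genes, 4533 (34.8%) were higher and 1271 (9.77%) lower after centring, with a centred median log2 ratio of 0.43. The counts of list members below are to be read against these shares. The deposited median log2 ratio was -0.96, a 1.94-fold loss. Over all 38439 probe sets these medians were 0.15 after centring and -1.23 as deposited. Each gene was represented by its probe set with the highest mean over all 6 arrays, quail included. Folds given as "at least" below are lower bounds on the deposited scale and include the loss across the array. A bound near 1.94 does not by itself show a loss beyond that of other genes. Of 20 gene lists tested with camera, 4 passed an adjusted p of 0.05: both transcription factor lists were shifted up, and the cytokine and the leukocyte antigen lists down, relative to all other genes. None of them passed with an estimated inter-gene correlation, where the adjusted p of the 4 lists was 0.295 to 0.316. On the deposited scale only the 2 transcription factor lists passed, while the cytokine and leukocyte antigen lists had adjusted p of 0.118 and 0.609, and none passed there with an estimated correlation (adjusted p = 0.966 for all 4). Values of camera below are from the centred signals unless the deposited scale is named. With chicken replicate 1, chicken replicate 2 or quail replicate 1 left out 1 list passed, without quail replicate 3 there were 2, and without quail replicate 2 there were 0.

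HOX and PAX factors, which pattern the embryonic axis and organs, lay nearer the chicken signal than other genes did, a shift past the threshold on both scales but not with an estimated correlation. Their deposited median log2 ratio was -0.35, 0.61 above that of other genes (camera adjusted p = 0.0268 after centring, and adjusted p = 0.295 with an estimated correlation). After centring 20 of 35 members were higher, 0 lower and 15 not past the threshold, with 23 higher and 0 lower when adjusted over the list alone. On the deposited scale 7 members were lower and 1 higher. HOXB4 had 23.4 ± 10.01 units in chicken and 56.6 ± 14.3 in quail (SD, n = 3), and PAX3 had 23.4 ± 13.8 and 40.4 ± 14.3, both called higher after centring and only HOXB4 on the deposited scale. The lowest members were HOXD4, with 41.5 and 12.1 units, and PAX5, with 48.4 and 21.6, neither past the threshold after centring.

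SOX, FOX, GATA and LHX factors, also developmental regulators, had a deposited median log2 ratio of -0.32, 0.64 above other genes (camera adjusted p = 0.0476 after centring, and adjusted p = 0.295 with an estimated correlation). The call held in 13 of 23 alternatives, with adjusted p from 0.000127 to 0.295. It was lost in 5 of the 6 settings with 1 array left out. Of 52 members 26 were higher, 3 lower and 23 not past the threshold, with 28 higher and 3 lower when adjusted over the list alone. FOXM1, a regulator of mitotic genes, went the other way, with 122 ± 14.4 units in chicken and 1.69 ± 0.849 in quail (SD, n = 3), at least 7.22-fold lower. FOXI1 had 143 ± 31.7 and 17.3 ± 9.12 units, and its call was lost without chicken replicate 2 or 3 (limma adjusted p = 0.0582 and 0.0526). FOXI2 had 12.1 units in chicken, within the null controls, and 25.2 in quail, and FOXD1 was within the null controls in both species. Both were called higher after centring, and the call of FOXI2 was lost without chicken replicate 3 (limma adjusted p = 0.0514). On the deposited scale 15 members were lower and 1 higher. These 2 lists also had dimmer chicken signals than other genes: the median log2 signal was 5.51 over both lists in chicken and 6.01 over all genes.

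Cytokines and chemokines were shifted down from other genes by -0.39, past the threshold after centring (camera adjusted p = 0.0476) but not on the deposited scale (adjusted p = 0.118) or with an estimated correlation (adjusted p = 0.316). The call held in 7 of 23 alternatives, with adjusted p from 0.0386 to 0.316. Their deposited median log2 ratio was -1.34. The centred median of the list was 0.04, against 0.43 over all genes. Its mean was -0.26, and camera's direction was down. After centring 7 of 55 members were higher, 8 lower and 40 not past the threshold, with 7 higher and 6 lower when adjusted over the list alone, and 41 were lower and 0 higher on the deposited scale. CXCL13L3 had 91.3 ± 1.96 units in chicken and 3.03 ± 0.881 in quail (SD, n = 3), at least 5.43-fold lower, and IL2, the T-cell growth factor, was at least 2.15-fold lower. IL18 and IL13 were the highest members, with 20.8 and 71.6 units in chicken and 26.1 and 85.3 in quail. The pattern that defined this list also caught receptor genes and IL4I1, an enzyme gene. Without them, a choice made after the data were seen, 41 members remained with an adjusted p of 0.139, and with such members removed from all lists only HOX and PAX factors passed. The SOX, FOX, GATA and LHX list and the leukocyte antigen list lost no members and kept their shifts. Their camera adjusted p became 0.0634 only through the adjustment over the lists. Leukocyte surface antigens were shifted by -0.58, past the threshold after centring (camera adjusted p = 0.0476) but not on the deposited scale (adjusted p = 0.609) or with an estimated correlation (adjusted p = 0.295). The call held in 7 of 23 alternatives, with adjusted p from 0.00670 to 0.680. Their deposited median was -1.54. After centring 8 of 44 members were higher, 8 lower and 28 not past the threshold, with 7 higher and 8 lower when adjusted over the list alone. On the deposited scale 32 members were lower and 0 higher. CD38, an NAD-hydrolysing enzyme of the cell surface, had 74.5 ± 7.52 and 1.43 ± 0.418 units (SD, n = 3), at least 4.42-fold lower in quail, and CD163L was at least 3.44-fold lower. CD40, at 12.7 units within the null controls in chicken, had 26.6 in quail, and CD69L was within the null controls in both species.

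Other immune lists did not pass. The toll-like receptors, sensors of microbial products, had a deposited median log2 ratio of -2.28, with a shift of -1.32 from other genes (camera adjusted p = 0.139). Of 8 members 2 were higher and 4 lower after centring, with 2 higher and 5 lower when adjusted over the list alone, and 6 were lower on the deposited scale. TLR2A had 49.8 ± 8.60 units in chicken and 1.33 ± 0.678 in quail (SD, n = 3), at least 2.93-fold lower, and TLR5 106 ± 19.0 and 16.7 ± 17.1. The call of TLR5 was lost without any 1 array except quail replicate 1 (limma adjusted p 0.0944 to 0.133). TLR21, with 66.7 and 62.0 units, and TLR15, with 63.3 and 55.9, were higher only relative to the array median. Cytokine receptors had 13 members higher, 10 lower and 35 not past the threshold of 58 (adjusted p = 0.139), the same 13 and 10 when adjusted over the list alone. IL22RA1 and CCR8 were the lowest, at least 2.73-fold and 3.28-fold lower. IL5RA, with 88.4 and 114 units, and CCR9, with 111 and 113, were the highest. The centred median of this list was 0.14, against 0.43 over all genes, and its mean -0.14. The MHC region list had 3 members higher and 4 lower of 15 (adjusted p = 0.158), or 4 and 6 when adjusted over the list alone. MHCY4, of the MHC-Y gene family, had 947 ± 84.0 units in chicken and 52.5 ± 18.5 in quail (SD, n = 3), 18.7-fold lower in quail on the deposited scale. Its quail value still lay above the mean quail array median of 20.5. DMBT1, which is no MHC gene but fitted the pattern of names, was at least 3.38-fold lower. BF2, a classical class I gene, had 98.7 and 119 units and was higher after centring, and BLEC1, with 14.9 and 27.8, was not past the threshold except without chicken replicate 3 or quail replicate 1 (limma adjusted p = 0.0224 and 0.0314).

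**Figure D3:**
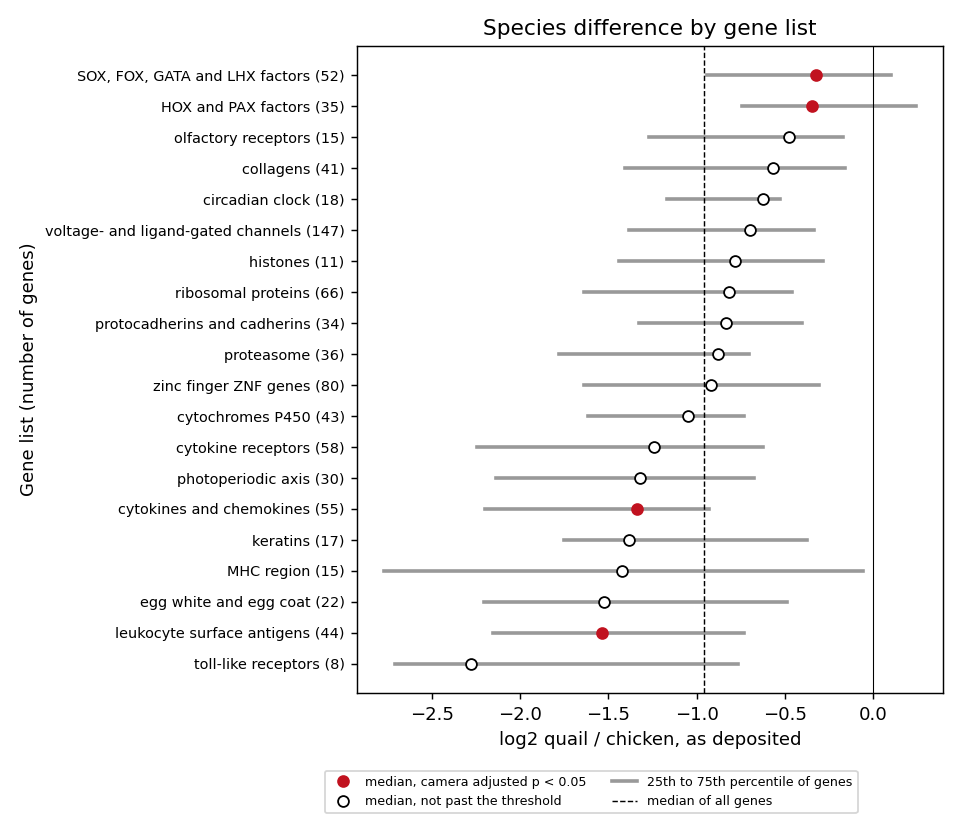
Median (points) and 25th to 75th percentile (bars) of the deposited log2 ratio of quail to chicken over the genes of each of 20 lists, n = 3 birds per species. Filled points mark the 4 lists past a camera adjusted p of 0.05 after centring, none of which passed with an estimated correlation, and the dashed line the median of all 13009 genes, -0.96. The list medians run from -2.28 for toll-like receptors to -0.32 for SOX, FOX, GATA and LHX factors.

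The photoperiodic axis, the thyroid hormone, opsin, melatonin and pituitary genes through which birds respond to day length, was a list of 30 genes and was not called as a group (camera adjusted p = 0.317, deposited median log2 ratio -1.32). After centring 9 members were higher, 5 lower and 16 not past the threshold, with 10 higher and 6 lower when adjusted over the list alone. On the deposited scale 21 were lower and 1 higher. THRA, a thyroid hormone receptor, was the member called higher on both scales, with 54.01 ± 13.04 units in chicken and 96.2 ± 22.98 in quail (SD, n = 3). DIO3, which inactivates thyroid hormone, had 23.5 ± 6.50 and 36.8 ± 8.93 units and was called higher only after centring. DIO2, which activates thyroid hormone, had 57.6 ± 2.54 and 36.5 ± 4.49 units (SD, n = 3) and was called higher after centring and lower on the deposited scale (limma adjusted p = 0.0323 and 0.0318). GPR50, with 83.8 and 52.8 units, turned in the same way. The centred call of DIO2 was lost without any 1 array except quail replicate 1 (limma adjusted p 0.0609 to 0.105), and that of GPR50 without chicken replicate 2 or 3 (limma adjusted p = 0.0693 and 0.0720). TSHB, the beta subunit of thyrotropin, had 77.3 ± 7.18 and 33.2 ± 8.29 units, close to the loss at the array median (centred log2 ratio 0.14, limma adjusted p = 0.596), and was lower on the deposited scale (limma adjusted p = 0.00397). Signals were nearly equal on the deposited scale for its receptor TSHR, with 96.9 and 94.2 units, for the deep-brain photopigment gene OPN5, with 73.6 and 72.2, and for TRHR, with 71.0 and 62.9. The lowest members were NPVF, the precursor of gonadotropin-inhibitory hormone, at 87.5 ± 25.3 and 5.21 ± 1.41 units (SD, n = 3) and at least 5.07-fold lower, POMC at least 2.33-fold lower, the melanopsin gene OPN4-1 at least 3.60-fold lower, and the melatonin receptor gene MTNR1A, with 125 and 10.8 units. TRH was lower too, with 109 and 19.4 units. The coactivator gene EYA3, with 80.2 and 37.1 units, and THRB, with 163 and 62.8, were not past the threshold after centring and were lower on the deposited scale. Without quail replicate 3 EYA3 passed as higher after centring (limma adjusted p = 0.0445). The centred median of this list was 0.06, against 0.43 over all genes, and its mean -0.04. Circadian clock genes had 9 of 18 members higher and 0 lower (adjusted p = 0.218), or 11 and 0 when adjusted over the list alone. CSNK1E and ARNTL had 43.6 and 76.9 units in chicken and 41.7 and 73.3 in quail, higher only relative to the array median. ARNTL2 and HLF, with 32.5 and 57.5 units in chicken and 5.13 and 14.0 in quail, were the lowest, not past the threshold after centring and lower on the deposited scale. ARNTL2 passed as lower after centring without quail replicate 1 and HLF without quail replicate 2 (limma adjusted p = 0.0272 and 0.0164).

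Among structural, metabolic and housekeeping lists none passed. The smallest adjusted p was 0.148, for the voltage- and ligand-gated channels, of which 67 of 147 members were higher and 11 lower (69 and 12 when adjusted over the list alone). KCNE4 was at least 6.07-fold and KCNA5 at least 1.70-fold lower in quail on the deposited scale. The bound of KCNA5 does not exceed the 1.94-fold loss at the median of all genes. KCNS1, with 46.6 and 87.5 units, and CHRNA10, with 17.4 and 27.4, were higher after centring only. The call of CHRNA10 was lost without chicken replicate 2, chicken replicate 3 or quail replicate 2 (limma adjusted p = 0.0620, 0.0628 and 0.0543). Collagens had 23 members higher and 3 lower of 41 (adjusted p = 0.218), or 25 and 3 when adjusted over the list alone. COL3A1, a fibrillar collagen, was an exception with 822 ± 72.5 units in chicken and 16.1 ± 9.45 in quail, and COL9A1 had 114 ± 7.87 and 9.30 ± 4.33 (SD, n = 3), with 1 of 3 quail above the null controls for each. COL14A1, with 93.3 and 179 units, was higher after centring, and COL18A1, with 16.7 and 21.8, was not past the threshold except without chicken replicate 3 (limma adjusted p = 0.0433). Ribosomal proteins had 24 of 66 members higher and 7 lower, the same when adjusted over the list alone (adjusted p = 0.725). RPL31 was at least 2.98-fold and RPL22L1 at least 2.10-fold lower. The call of RPL31 was lost without chicken replicate 1 or 3 (limma adjusted p = 0.0718 and 0.0689) and that of RPL22L1 without chicken replicate 3 (limma adjusted p = 0.0501), while RPS28, with 17.9 and 44.5 units, was higher after centring only. Proteasome genes had 9 higher and 4 lower of 36, also when adjusted over the list alone, with PSMG4 at least 4.19-fold lower and PSMB7 at 101 and 125 units. Their median shift was 0.08 above other genes whereas camera's direction was down (adjusted p = 0.663). Histones had 4 higher and 0 lower of 11, also when adjusted over the list alone (adjusted p = 0.654), with H1FOO at 65.3 and 77.8 units.

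Protocadherins and cadherins had 14 higher and 1 lower of 34, or 15 and 1 when adjusted over the list alone (adjusted p = 0.237), with PCDH18 at 67.2 and 11.2 units and CDH4 at 64.4 and 81.1. Without chicken replicate 1, 2 or 3 the call of PCDH18 was lost (limma adjusted p = 0.101, 0.113 and 0.0930). The ZNF zinc finger genes had 36 higher and 7 lower of 80, or 37 and 10 when adjusted over the list alone (adjusted p = 0.654), and ZNF512 was at least 3.80-fold lower. Cytochromes P450 had 11 higher and 4 lower of 43, also when adjusted over the list alone (adjusted p = 0.725), with CYP4A22 at least 4.001-fold lower and CYP11A1 at 41.6 and 51.3 units. Egg white and egg coat genes had 7 higher and 4 lower of 22, or 8 and 4 when adjusted over the list alone (adjusted p = 0.296). OVAL, which encodes ovalbumin, was at least 2.07-fold lower, a call lost without chicken replicate 1 or 3 (limma adjusted p = 0.0513 and 0.0512), and the egg coat gene ZP3L1 had 65.5 and 79.0 units. Keratins had 6 higher and 3 lower of 17, or 6 and 4 when adjusted over the list alone (adjusted p = 0.663), with KRT3 at least 3.08-fold lower and KRT14 at 57.3 and 77.3 units. The keratin mean was 0.14 after centring while camera's direction was down, and up on the deposited scale. The patterns of both the keratin and the egg list also caught genes outside their name. Without them, a choice made after the data were seen, 15 keratins remained (camera adjusted p = 0.789) and 20 egg genes (camera adjusted p = 0.167). The shift of the keratins from other genes was then -0.062 instead of -0.43, and that of the egg genes -0.71 instead of -0.57. Olfactory receptors had 8 higher and 2 lower of 15, also when adjusted over the list alone (adjusted p = 0.317), with OLFR6 at least 3.63-fold lower, a call lost without chicken replicate 3 (limma adjusted p = 0.0518), and OR5AP2 at 75.5 and 101 units.

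Chromosome positions were taken from the GRCg7b annotation of the chicken genome. Genes on chromosome Z, of which a female bird carries 1 copy, gave less signal than autosomal genes in both species. The median of 604 Z-linked genes minus that of 12203 autosomal genes was -0.69 ± 0.04 (log2) in chicken and -0.64 ± 0.07 in quail (SD, n = 3), and the species difference of 0.05 was within the spread between birds (exact two-sided permutation p = 0.4). With quantile normalization that difference was 0.53, and with means above the median 0.17. Genes on chromosomes 11 to 39 were compared with those on chromosomes 1 to 5 and Z. Their median difference was -0.05 ± 0.01 in chicken and 0.11 ± 0.02 in quail (SD, n = 3), without overlap between species (exact permutation p = 0.1, the smallest possible). The species difference of 0.16 fell to 0.070 with 64 units added. The deposited median log2 ratio was -1.02 over 6355 genes on chromosomes 1 to 5 and Z, -1.01 over 2065 genes on chromosomes 6 to 10 and -0.83 over 4387 genes on chromosomes 11 to 39. Among chromosomes with at least 20 genes, medians of -0.56 over 99 genes on chromosome 34 and -0.53 over 21 genes on chromosome 38 were the nearest to 0, and -1.47 over 24 genes on chromosome 30 the lowest. The 17 genes assigned to W had a median of -1.43.

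**Figure D4:**
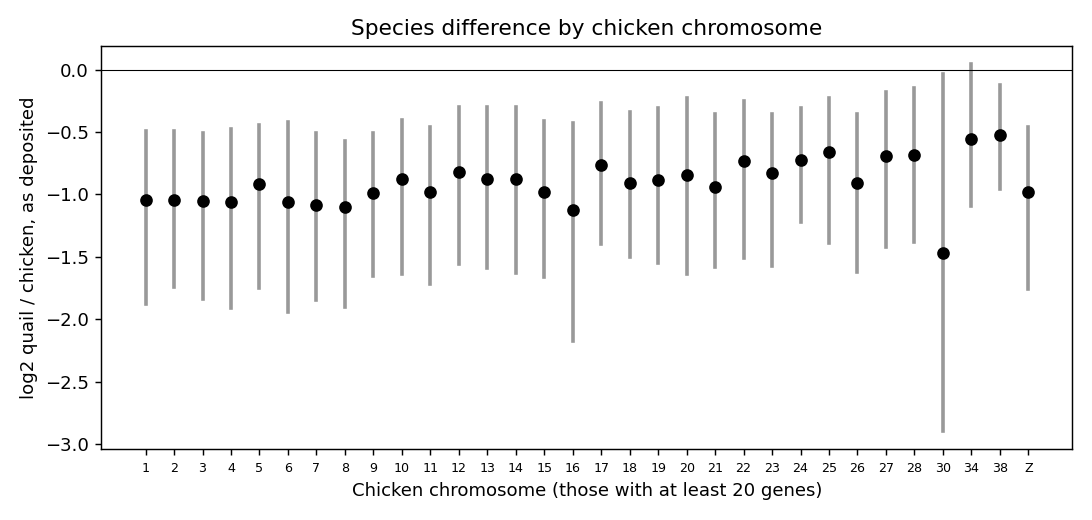
Median (points) and 25th to 75th percentile (bars) of the deposited log2 ratio of quail to chicken over genes of each chicken chromosome with at least 20 genes, n = 3 birds per species. Medians lie near -1.05 on chromosomes 1 to 4 and at -0.56 and -0.53 on chromosomes 34 and 38, while chromosome 30 lies at -1.47.

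Probe set classes were compared on the deposited scale. Probe sets with plain names ending in _at had a deposited median log2 ratio of -1.32 (27971 probe sets), against -1.14 for _a_at (1756), -1.01 for _s_at (8252) and -1.07 for _x_at (460), endings that mark probes matching several transcripts. The species difference of _s_at minus _at, from medians per array, was 0.40, and it fell to 0.15 with quantile normalization and 0.11 with means above the median. The order of _x_at and _at depended on the measure. From medians per array, quail minus chicken was -1.52 for _x_at and -1.49 for _at. After centring, 22.8% of _x_at probe sets were called lower and 28.0% higher, against 16.9% and 22.4% of _at. The per-array medians of each of these classes were lower in all 3 quail than in all 3 chickens (exact permutation p = 0.1 each, the smallest possible). The Gga probe sets had a median of -1.43 and the GgaAffx probe sets -1.06. The 57 reporter probe sets and 689 probe sets from other sequence records gave 0.02 and -0.02, at median signals of 4.48 ± 1.45 and 2.65 ± 0.248 units in chicken (SD, n = 3), near the null control median of 3.32 ± 0.601. After centring, 36.8% of the reporter and 21.8% of the other-record probe sets were still called higher, and 0% and 0.726% lower. Of all tested probe sets 24.5% were called higher, so a centred call of higher does not require signal above background.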

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

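The tests of the overall signal difference were chosen only after that result was seen, as were the binomial intervals used for the probe sets higher in quail. The permutation tests of the chicken gene controls were not among those written down before. The remaining tests in this part were written down before, but the null control level that some of them use was set after the data were seen.

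Control probe sets of chicken genes, which no comparison used, gave signal above the null controls on all 6 arrays at 7 of 10. Quail over chicken was 0.690 for actin-5 (47.6 ± 1.61 in chicken and 33.0 ± 3.85 in quail, SD, n = 3), 1.95 for actin-M (22.03 ± 2.70 and 43.2 ± 8.14), 0.465 for ef1a-3, 0.657 for ef1a-M and 0.522 for gapdh-3, each with an exact permutation p of 0.1, the smallest possible. It was 0.893 for gapdh-5 (exact permutation p = 0.5) and 1.19 for gapdh-M (exact permutation p = 0.4). These are ratios of deposited signals, and parts of 1 gene went in different directions.

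Quail signal lay below chicken signal on most probe sets as deposited. A factor that lowers all signals in the same proportion does not account for it alone. Over 15773 probe sets above the null controls on all arrays the interquartile range of the log2 ratio was 2.42 times that of the noise between birds of a species, where such a factor gives about 1. The test does not cover a factor whose effect changes with signal level, and the loss was 4.29-fold at the 25th percentile and 1.95-fold at the 75th. Less labelled quail DNA is therefore not excluded as the only cause. Weaker hybridisation, staining or scanning is argued against by the spike-ins, which differed by 0.0089 (log2, SE 0.075 with arrays unpaired). However, the spike-ins are added after labelling and do not cover the amount of labelled DNA. A sequence difference between quail DNA and chicken probes was not decided: after removal of the trend with chicken signal, the 87 transcription factor genes lay above 107 immune genes by 0.97, but these lists were picked after their shifts were seen. It stays open, as does a common factor beside it, since probe sequences were not available.

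At 421 probe sets quail was higher on both scales. Noise of dim probe sets was not decided: 75.1% (95% exact Clopper-Pearson interval 70.6 to 79.1) lay above the null controls in all 3 quail, but they were selected for high quail signal, the interval does not clear the bound of 75% set beforehand, and 37.1% lay within the null controls in all 3 chickens. Only 384 of the 421 had Gga or GgaAffx names. The reporter and other-record probe sets had median signals near the null control median. As deposited, 8.77% of reporter probe sets were higher and 3.51% lower, and 4.64% and 4.79% of the other-record ones. The share higher was 0.906% for Gga and 1.17% for GgaAffx probe sets. Probes that match several transcripts were not decided either: the share of names ending in _s_at or _x_at was 0.964 times that among all tested (interval 0.794 to 1.15), below the 1.5 predicted but not clear of the bound of 1.1, and 3.48% of _x_at probe sets were higher as deposited against 1.13% of _at, 0.921% of _s_at and 0.740% of _a_at. Whole genes at higher copy number in quail remain undecided: 18.9% of 435 other probe sets of these genes (interval 15.3 to 22.8) had a ratio above 0, far below the 50% predicted of this cause, but the interval does not clear the bound of 10 points above the 9.11% among probe sets of genes with several, and the loss across the array lowers these probe sets too. No biological explanation could be separated from the species itself.

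The HOX, PAX, SOX, FOX, GATA and LHX genes lay nearer the chicken signal than other genes. Their lower chicken signal is argued against as the whole cause: the list median exceeded the median of 10000 sets matched on chicken signal by 0.56, and none of these sets reached it. These lists were picked after their shifts were seen, so part of that excess follows from the choice. The matched sets themselves had a median log2 ratio of -0.91 as deposited, near the -0.96 of all genes. If the choice of the brightest probe set made the shift, it was predicted to fall when chicken signal alone chose the probe set. It was 0.78 instead, against 0.61. That choice changed the probe set of 1785 genes and favours high chicken signal, which by itself lowers ratios. It therefore cannot tell how much the choice of probe set adds to the shift. The matched sets ignore correlation between genes, the calls of these lists were lost with an estimated correlation, and cross-hybridisation between paralogs was not tested. Slower sequence change in these genes was not measured and stays a hypothesis.

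The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05, and only 1 split, the real one, gave a result as large for each of these. The real values and the highest among the other splits were 6012 and 0 for lower, 9415 and 0 for higher, 5611 and 0 for at least 2-fold lower, 6306 and 0 for at least 2-fold higher, 21671 and 15614 for retained probe sets, and 4 and 2 for gene lists. Every other split puts birds of both species in both groups, so the species difference adds to the spread within groups. Lower counts of probe sets are thus built into these splits, and they do not measure chance.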

How the results depend on the processing

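The alternatives with 16 units added to deposited values, with chicken signal above the null controls and with lists without outside members were chosen after seeing the data. Scaling decided which probe sets were called, because the deposited values keep the lower total signal of quail: 1166 calls changed direction and 7828 were lost as deposited; the cause of the other changes was not tested. Under values as deposited, spike-in centring and deposited values plus 16, the counts were 22863, 23479 and 24354 lower, 421, 435 and 501 higher, 20035, 20234 and 14173 at least 2-fold lower, 320, 318 and 1.2e+02 at least 2-fold higher, and 6424, 6607 and 13958 retained. Centring on the 75th percentile gave 8980 lower, 4697 higher, 8189 at least 2-fold lower and 2432 at least 2-fold higher, and only _at names gave 6224 higher, with fewer probe sets tested. Means above the 25th percentile or the median left fewer probe sets and gave 3316 or 1476 lower and 2897 or 1019 at least 2-fold lower. With 16 or 64 units added, 3233 or 342 were at least 2-fold lower and 3082 or 383 at least 2-fold higher, and with 64 units 37770 were retained. Leaving out 1 array gave 3150 to 6583 lower, 6692 to 9005 higher, 3081 to 6102 at least 2-fold lower, 5264 to 6289 at least 2-fold higher and 19949 to 21903 retained. With replicate number as a block, the counts stayed within 1.5 times.

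Of the 4 lists called, 2 were called as deposited, 2 with quantile normalization, 2 with spike-in centring, 2 without the intensity trend, 2 with only _at names, 2 with deposited values plus 16, 2 with chicken signal above the null controls, 2 with the mean of all probe sets, 1 above the median, 1 without outside members, 0 above the 25th percentile and 0 with an estimated correlation; fry, which asks another question, called 15. Leaving out 1 array gave 0 to 4, with 0 without quail replicate 2. Over 23 alternatives HOX and PAX factors stayed called in 19 (adjusted p 2.87e-06 to 0.295), SOX, FOX, GATA and LHX factors in 13 (0.000127 to 0.295), cytokines and chemokines in 7 (0.0386 to 0.316) and leukocyte antigens in 7 (0.00670 to 0.680), with the sign of the shift the same in all 23.

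The species difference of _s_at minus _at was 0.40 as reported, 0.15 with quantile normalization, 0.28 and 0.15 with 16 and 64 units added, and 0.23 and 0.11 with means above the 25th percentile and the median. That of Z minus autosomes was 0.05 as reported, 0.53 with quantile normalization, and 0.15 and 0.17 with means above the 25th percentile and the median. That of chromosomes 11 to 39 minus 1 to 5 and Z was 0.16 as reported and 0.12 and 0.070 with 16 and 64 units added. The median SD between quail was 0.46 as reported, 0.37 with quantile normalization, 0.27 and 0.14 with 16 and 64 units added, 0.39 and 0.32 with means above the 25th percentile and the median, and 0.36 to 0.46 with 1 array left out. The spike-in difference was 1.39 after median scaling and 0.0089 as deposited.

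Genes with a positive centred ratio turned negative under values as deposited, spike-in centring and deposited values plus 16, in that order: TLR21 at -0.11, -0.11 and -0.085, TLR15 at -0.18, -0.18 and -0.14, CSNK1E at -0.025, -0.034 and -0.027, ARNTL at -0.065, -0.074 and -0.054, DIO2 at -0.66, -0.67 and -0.49, EYA3 at -1.28, -1.29 and -0.93, GPR50 at -0.70, -0.71 and -0.56, and MTNR1B at -0.85, -0.86 and -0.67. So did OPN3 at -0.41, -0.42 and -0.34, OPN5 at -0.010, -0.019 and -0.011, PRL at -1.19, -1.20 and -0.92, TRHR at -0.16, -0.17 and -0.13, TSHB at -1.25, -1.26 and -0.94, TSHR at -0.052, -0.061 and -0.043, TTR at -1.36, -1.37 and -0.99, and VIP at -0.89, -0.90 and -0.71. CCR9 gave -0.0059 with spike-in centring, and AANAT ran from -0.58 without quail replicate 3 to 0.74 without quail replicate 2. Background limits dim probe sets: 56.3% of probe sets lay above the null controls in quail, so that larger losses are lower bounds.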

Other observations

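The groups in this part were chosen after the values were seen. Probe sets with more than 4 times the array median in all birds of a species numbered 381 in chicken and 909 in quail, with 125 in both where independence gives 9.01. The array medians were 50.02 to 56.2 units in chicken and 17.3 to 22.4 in quail. The limit was therefore lower in quail, and the counts of the species do not refer to equal signals. Those bright in chicken had median signals of 428 units in chicken and 39.3 in quail, and 89 of them (23.4%) were within the null controls in all 3 quail, close to the 23.1% of other probe sets above the null controls in all 3 chickens. LIMS1 and TARP had 5 bright probe sets each in chicken, ARL2BP had 3, and BKJ, CHIR-A2, HINTW and LOC776593 had 2. In quail 31 genes had 2 bright probe sets each, AFF4 and DMRT3 among them. Those bright in quail had median signals of 122 units in chicken and 117 in quail, and 2 of them were within the null controls in all 3 chickens.

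Some probe sets without a gene symbol gave the largest excess of quail signal. The highest had 128 ± 8.66 units in chicken and 5661 ± 661 in quail (SD, n = 3), 44.0-fold higher as deposited, and another had 73.8 ± 5.59 and 1665 ± 101 units, 22.6-fold higher. A further one had 458 ± 28.6 units in chicken and 8627 ± 446 in quail (SD, n = 3), where it was the highest of the tested probe sets on each array.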
